A study of Drosophila melanogaster with 2 samples.

How the data were processed

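The samples were chromatin immunoprecipitations with an anti-GFP antibody from whole embryos (0 to 24 h) of a fly line carrying chm-eGFP, sonicated before the precipitation, per the labels. The 2 samples are biological replicates of 1 group, taken from the replicate number in the labels. The deposited files are peak lists on the dm6 assembly, per the file names, called per sample and on the reads of both samples together; the aligner and peak caller are not given in the sources used here. The file notes name further inputs that they do not describe, and the labels name a possible control experiment, whose data were not used here.

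Each list comes as ranked peaks and as peaks past a threshold on the irreproducible discovery rate (IDR), a measure of how well ranks agree between 2 sets of peaks. The deposited score column is a scaled IDR score, at least 830 in every list past the threshold. The deposited signal column is the peak caller's signal value, whose scale is not given. Signals were compared within a list, except that the signals of the replicates were correlated across peaks and averaged per named peak, where the SD also holds any difference in scale between the replicates. The deposited −log10 columns hold the q-value of the peak caller and the local and global IDR. Every peak past the threshold had a global IDR of at most 0.01 in the matching ranked list, but 195 of 4397 such peaks were missing from the conservative list, 252 of 6428 from the pooled list, 192 of 3746 from replicate 1 and 176 of 4282 from replicate 2, for a reason that the sources used here do not give. The ranked lists held 118204 (pooled), 108273 (replicate pair), 104106 (replicate 1) and 88563 (replicate 2) peaks. The pooled list had 1.47 times as many peaks as the conservative list and the larger replicate list 1.16 times as many as the smaller. Of the conservative peaks, 3820 were in the pooled list with the same ends. The ranked list that pairs the replicates gives a signal from each replicate for every peak, without naming the replicates, and these 2 values give the replicate mean and SD of each named peak.

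Computed here, from these lists: peak summits on X, 2L, 2R, 3L, 3R, 4 and Y were placed on the gene models of Ensembl release 115 (BDGP6.54) and the RefSeq sequence of release 6, whose arm lengths contain all peaks. Summits were classed, in this order, as promoter (within 500 bp of a protein-coding transcript start), 5' UTR, coding exon, 3' UTR, other exon, intron or intergenic, and compared with the share of non-N bases in each class by exact binomial tests. Chromosome arms and non-coding gene classes were tested in the same way, and adjusted p-values follow Benjamini and Hochberg within each family. Genes with a promoter peak were counted in 30 gene lists by two-sided Fisher's exact tests, beside a test that shifted gene labels along the genome order in 10000 draws. The 20 motifs were searched on both strands within 100 bp of each summit and of a point 1000 bp away (exact McNemar test). They were also searched within 250 bp of 1 start per gene in bound and unbound promoters (Fisher's exact test). That start was the one nearest a summit in bound genes and the first annotated 5' start in the others. Replicate overlap asked for 50% of the shorter peak and was compared with 100 circular shifts. Median signals were compared by a permutation test of 100000 draws. Shares are given with 95% Wilson intervals, and a share of 0 also with the limit of 3 counts of the total, a one-sided limit; both cover counting error only. With 2 replicates, SDs describe these samples.

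The gene lists were JNK pathway and epithelial closure, Hox cluster, Polycomb targets, Polycomb group, trithorax group, acetyltransferases and partners, replication initiation, cell cycle, replication-dependent histones, chorion, cytosolic ribosomal proteins, proteasome, oxidative phosphorylation, translation initiation, heat shock, chemosensory receptors, cuticle, gut serine proteases, gap and pair-rule, dorsoventral, early zygotic, Notch and E(spl), ecdysone response, and markers of neuroblasts, neurons, glia, muscle, hemocytes, trachea and germline. Some genes are in more than 1 list, such as dpp, ush, cad, Dp and the Doc genes. A few listed symbols were matched to the annotation's current names, such as hry for h and Delta for Dl, and 17 listed ecdysone response symbols gave 16 genes. The lists, motifs, tests and the rule for named genes were fixed before the data were examined: chm, the nearest protein-coding gene of the 25 strongest main-list peaks whose summit lay in a peak of both replicates, and per list the 4 members with the strongest promoter peak, with up to 2 members without a peak where a list had few. Other members named for a list's make-up (such as bsk, kay and Jra), neighbours that share a peak (mRpS23, mRpS10), and the summary of the replicates' differences, were chosen after their values were seen.

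The tests were tested on simulated data. Of 4 lists whose members were given promoter peaks more often, among 13968 genes, 3 were recovered for the gene list test, and 0 of 22 unchanged lists were called. Of 4195 simulated summits placed at promoters at 55.6%, 56.2% were found there for the location test, and 0 of 7 classes were called with random summits. A DRE planted so that 5.08% of 4195 summits carried one was found in 5.08% for the motif test at summits, and 0 of 20 motifs were called without planting. For the comparison of bound with unbound promoters, 0 of 20 motifs were called for random genes among 13968. That simulation held no peaks, so it did not test the choice of the start nearest a summit in bound genes. For replicate overlap, 50% of 4195 simulated peaks were shared by construction and 51.3% were found. Alternatives tried were the pooled list, each replicate's own list, the stronger 50% of peaks, merged peaks, promoter windows of 250 and 1000 bp, other backgrounds and other motif windows. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.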

Results

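Chromatin from whole Drosophila melanogaster embryos collected 0 to 24 h after egg laying was immunoprecipitated with an antibody against GFP from transgenic flies that express chameau (chm) fused to eGFP, and the recovered DNA was sequenced. Chameau is a histone acetyltransferase of the MYST family, known from genetic work as a partner of Polycomb group genes and as a cofactor in JNK signalling. The 2 samples were biological replicates 1 and 2 of a single group, so no group was set against another, and the comparisons below place the peaks against the genome, against other genes and against neighbouring sequence. The peak lists give no read totals, so the sequencing depth behind each peak is unknown. Replicate 1 had 3554 peaks past the reproducibility threshold and replicate 2 had 4106. The conservative list, taken from the ranked peaks matched between the replicates, held 4202 peaks, of which 4195 lay on the 7 chromosome arms tested, and is the main list throughout. The pooled list, the other series-wide list past the threshold, held 6176.

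The first question was how far the replicates gave the same binding sites. Of the replicate 1 peaks, 1965 (55.3%, 95% Wilson interval 53.7 to 56.9%) were overlapped by a replicate 2 peak over at least 50% of the shorter peak, and 48.1% (46.6 to 49.6%) of the replicate 2 peaks were overlapped in return. When 1 list was shifted along the chromosomes, 0.927% of peaks overlapped on average over 100 draws and 1.33% at most, which gave a permutation p of 0.0099, the smallest that 100 draws allow. Of the main-list peaks, 1944 (46.3%) were in the lists of both replicates and 825 (19.6%) in neither. Peaks outside the overlap had a median signal of 47.4 against 70.5 for shared peaks in replicate 1. In replicate 2 these medians were 43.2 and 65.3. A further 79.7% of the unshared replicate 1 peaks and 66.0% of the unshared replicate 2 peaks overlapped a peak of any rank in the other replicate. The ranked lists are long, and with them shifted along the chromosomes these shares were 19.6% and 22.6% on average and 22.3% and 25.3% at most (both permutation p = 0.0099, 100 draws, a test added after the data were seen). None of these shifts kept peaks at promoters, where 46.7% of replicate 1 and 55.6% of replicate 2 summits lay. Overlap beyond this shared preference was thus not tested. Across the 1965 shared peaks the signals of the replicates correlated with a Spearman rho of 0.584 and a Pearson r of 0.661 on the log2 scale; these are correlations across peaks, which are not independent replicates.

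**Figure D1:**
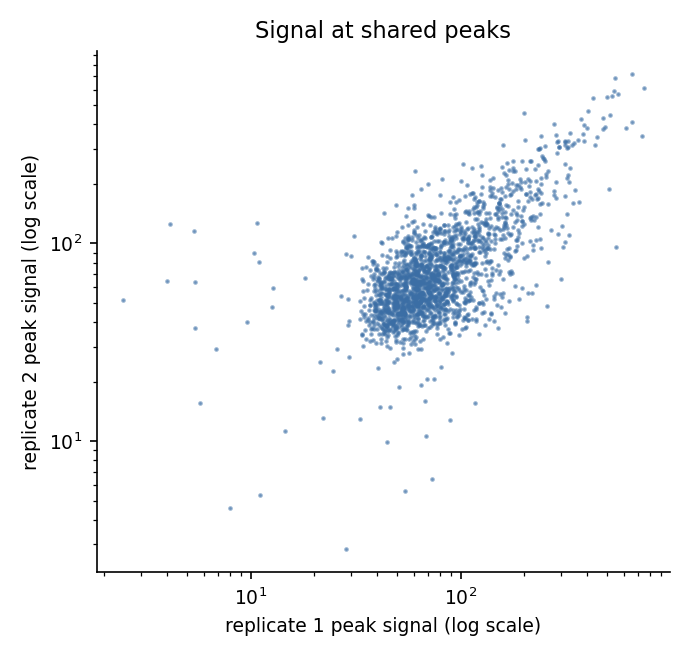
Peak signal in replicate 1 (horizontal axis, log scale) against replicate 2 (vertical axis, log scale) for the 1965 replicate 1 peaks that overlap a replicate 2 peak; each point is a peak. The Spearman rho is 0.584, and the signal scales of the replicates may differ, so only the order of peaks is to be read.

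Chameau-eGFP peaks lay mainly at the starts of protein-coding genes. In the main list 2159 of 4195 summits (51.5%, 95% Wilson interval 50 to 53.0%) fell within 500 bp of a protein-coding transcript start. This region makes up 11.2% of the genome, a 4.59-fold excess. The lists of the separate replicates gave 51.1% ± 6.29 (SD, n = 2). Exons annotated to no coding or untranslated class held 3.27% of summits against 1.61% of the genome (2.03-fold, adjusted p = 6.69e-14, exact binomial test) and 5' UTRs outside promoters held 1.14% against 0.774% (1.48-fold, adjusted p = 0.0102). Coding exons held fewer summits than their share, with 1.43% of summits against 13.6% of the genome (0.105-fold, adjusted p = 8.36e-180, exact binomial test), as were 3' UTRs with 0.93% against 4.42% (0.21-fold, adjusted p = 1.04e-39). Introns held 28.7% of summits against 39.6% (0.726-fold) and intergenic sequence 13.0% against 28.8% (0.452-fold), so 1206 and 546 peaks still lay in those classes. The median distance from a summit to the nearest protein-coding start was 444 bp, with 31.9% of summits within 100 bp of one and 17.3% beyond 5000 bp. Promoter peaks had a median signal of 98.9 against 89.7 for the other peaks, a difference of 9.23 (two-sided permutation p = 1e-05, the smallest that 100000 draws allow).

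**Figure D2:**
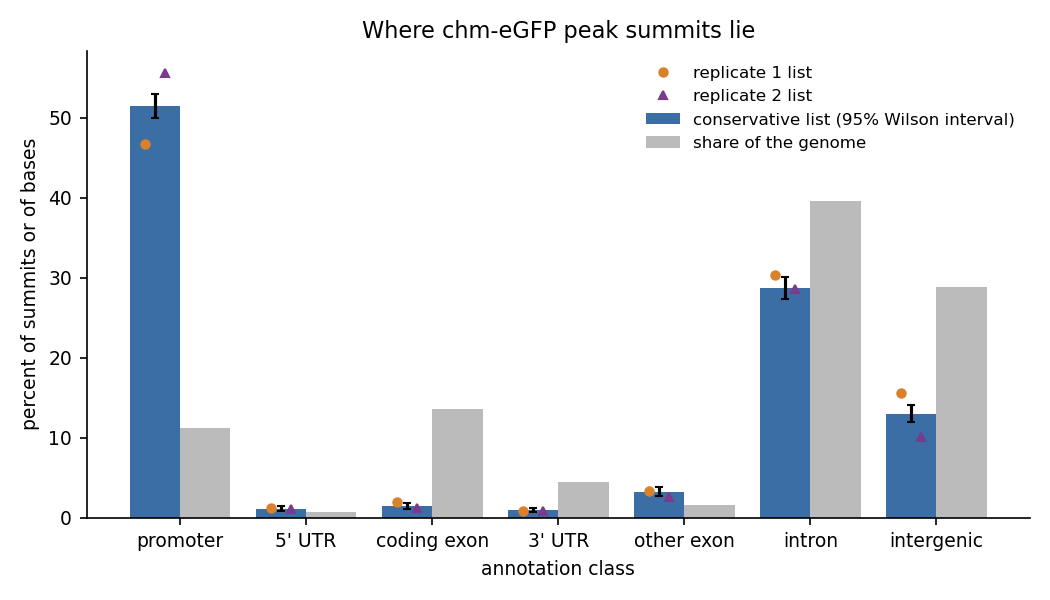
Percent of peak summits (blue bars, conservative list, with 95% Wilson intervals) and percent of the genome (grey bars) in 7 annotation classes; orange points are the replicate 1 list and purple triangles the replicate 2 list. Promoters hold 51.5% of summits and 11.2% of bases, while introns, intergenic sequence and coding exons hold fewer summits than their share of bases.

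Peaks were spread over the large arms and sparse on the small chromosomes. Chromosome 4 carried 16 peaks, 12 per Mb and 0.393 of the number its bases would give (adjusted p = 8.49e-05, exact binomial test). Against its share of protein-coding genes the ratio was 0.666 and was not called (adjusted p = 0.172, exact binomial test). The Y chromosome carried 0 of the 4195 peaks (adjusted p = 3.47e-45 against its bases, exact binomial test), although 306 of the ranked peaks of any strength lay there. Whether peaks can be called as readily on the Y as on other arms was not tested. The X held 15.2% of peaks against 17.1% of bases (0.885-fold, adjusted p = 0.00174, exact binomial test), but against its share of genes the ratio was 0.964 (adjusted p = 0.361). Arm 3L held more peaks than its bases (1.08-fold, adjusted p = 0.0138) and than its genes (1.13-fold, adjusted p = 0.000183) would give by exact binomial tests. Arms 2R (1.15-fold, adjusted p = 7.56e-05, exact binomial test) and 2L (1.07-fold, adjusted p = 0.0466) held more than their bases would give, but against their genes the ratios were 1.03 (adjusted p = 0.329) and 0.969 (adjusted p = 0.361), without a call by exact binomial tests. Arm 3R held fewer than its genes would give (0.93-fold, adjusted p = 0.0179, exact binomial test), and against its bases 0.974-fold (adjusted p = 0.372). In the replicates, the X took 14.8% ± 0.908 (SD, n = 2) of peaks and 3L 22.7% ± 0.959 (SD, n = 2).

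Named individually are the nearest protein-coding genes of the 25 strongest main-list peaks whose summit lay in a peak of both replicates. Their signals ran from 689 to 1374, and 17 of the 25 summits were at promoters. The strongest peak (X, 2703763 to 2704034, dm6) lay 49 bp from a start of Ugalt, which encodes a UDP-galactose transporter, with a pooled signal of 1374 and a replicate signal of 683 ± 46.5 (SD, n = 2). The next lay 99 bp from CG14100 (3L, 19590479 to 19590758; pooled signal 1350, replicates 678 ± 92.6, SD, n = 2) and in an intron of CG11050 (2L, 6612401 to 6612970; pooled signal 1295, replicates 612 ± 101, SD, n = 2). CenG1A (pooled signal 1122), the arginine methyltransferase gene Art3 (1087), px (1082), CG1888 (1055), CG18549 (1051) and the Polycomb group gene ph-p (993) followed with promoter peaks. The ph-p summit lay inside the gene, 497 bp from the start and so at the edge of the 500 bp window. The CenG1A and Art3 peaks also lay at promoters of mRpS23 and mRpS10, which encode mitochondrial ribosomal proteins. The replicate signal at px was 539 ± 269 (SD, n = 2). PNPase, an exoribonuclease gene, Tcs5, a tRNA modification gene, and mRpL41, another mitochondrial ribosomal protein gene, had promoter peaks of signal 975, 888 and 886. CG9147 (866), Chro (856), which encodes a chromosomal protein of the spindle matrix and interbands, RluA-1 (805), CG8320 (770), Fkbp14 (699) and MFS10 (699) completed the promoter peaks. The other summits were distal. They lay in introns of Tlk (signal 781) and CG32772 (760) and in an exon of the long non-coding RNA gene CR31840 near hll (689). Intergenic summits lay 1305 bp from DNAlig3 (1109), 3161 bp from tara (747), 5726 bp from eEF1gamma (780) and 11911 bp from CG13323 (950). At hll the replicate signal was 349 ± 227 (SD, n = 2).

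A promoter peak was found at 2350 of 13968 protein-coding genes (16.8%, 95% Wilson interval 16.2 to 17.5%), and 15.3% ± 2.63 (SD, n = 2) of genes had one in the separate replicate lists. Of 30 gene lists, 8 had promoter peaks more often than the remaining genes, 4 less often and 18 gave no call (Fisher's exact test, two-sided, adjusted over the 30 lists). A second test that shifts gene labels along the genome order, and so keeps clustered families together, gave an adjusted p under 0.05 for 7 of the 12 called lists.

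The genes of the cytosolic ribosome stood furthest above the rest. Of 82 ribosomal protein genes, 62 (75.6%, 95% Wilson interval 65.3 to 83.6%) had a promoter peak against 16.5% of other genes (adjusted p = 2.82e-30, Fisher's exact test). The shift test gave an adjusted p of 0.0015, the smallest that its permutation draws allow here, and the replicate lists gave 73.2% ± 3.45 (SD, n = 2). The strongest were RpL7 (2L, 10200939 to 10201138, 38 bp from the start) with a pooled signal of 492 and 243 ± 99.3 in the replicates, RpS27 with 412 (210 ± 42.2), RpL23A with 337 (162 ± 47.0) and RpL24 with 327 (162 ± 7.93; all SD, n = 2). Translation initiation factors had a peak at 14 of 44 genes (31.8%), among them eIF6 (627), eIF4EHP (333), eIF1 (292) and eIF3h (157). Their adjusted p was 0.0372 by Fisher's exact test and 0.0702 by the shift test. This call was lost in 8 of 11 other settings, the lists of replicate 1 (25%, adjusted p = 0.0966) and replicate 2 (27.3%, adjusted p = 0.226) by Fisher's exact test among them. Subunits of the proteasome (5 of 48, 10.4%; Rpn9 105, Rpn3 104, Rpn5 88.5, Prosbeta5 83.1) and of oxidative phosphorylation (11 of 84, 13.1%; ND-ASHI 291, COX5A 169, COX7C 160, COX6B 108) did not differ from other genes, with adjusted p of 0.398 and 0.515 by Fisher's exact test.

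**Figure D3:**
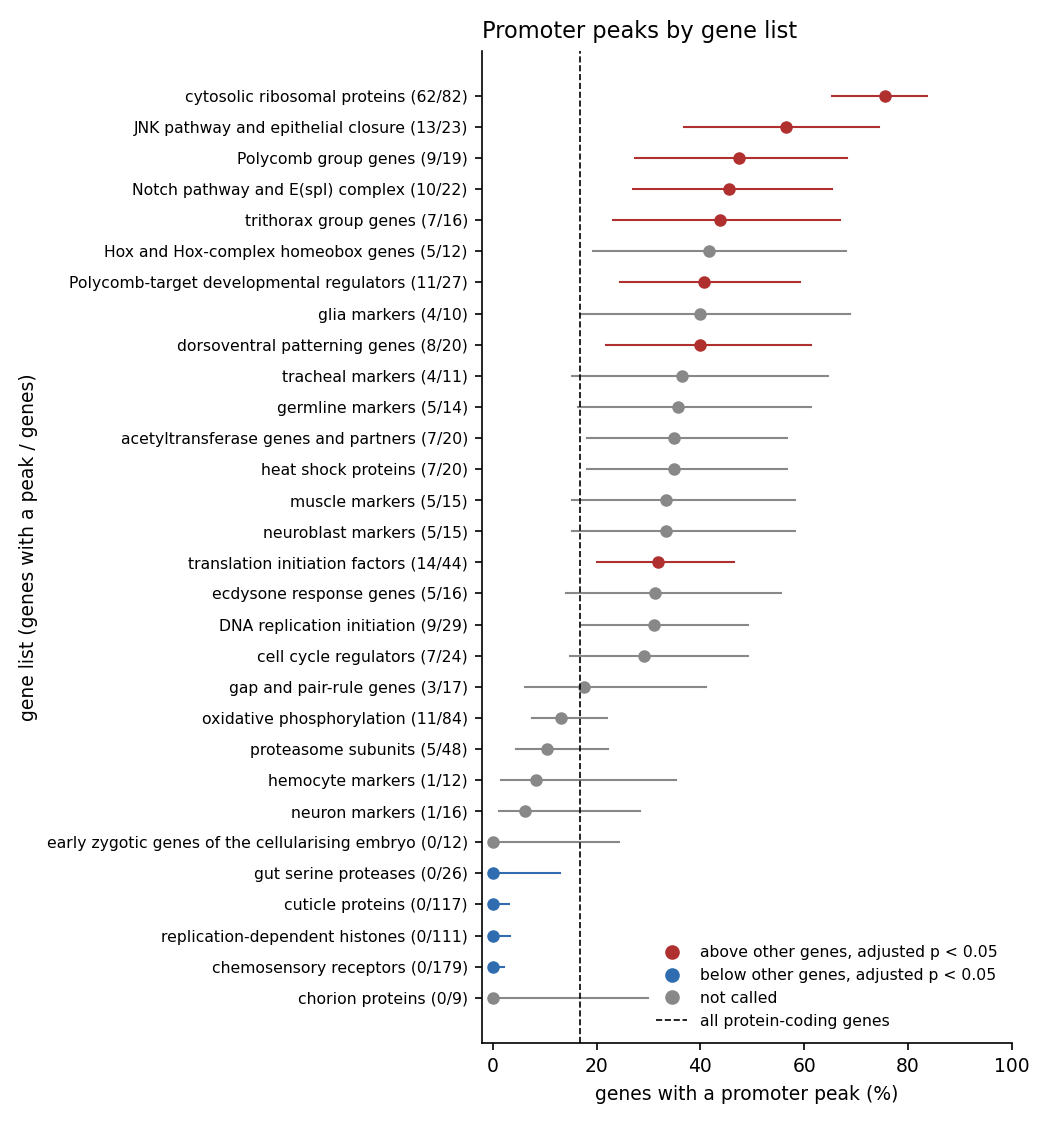
Percent of the genes in each of 30 lists with a chm-eGFP promoter peak (points, with 95% Wilson intervals); red lists lie above the other genes, blue lists below them, grey lists gave no call, and the dashed line marks all protein-coding genes at 16.8%. Cytosolic ribosomal protein genes reach 75.6%, and chemosensory receptor, cuticle protein and histone genes are at 0.

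JNK signalling and epithelial closure genes had promoter peaks at 13 of 23 members (56.5%, 95% Wilson interval 36.8 to 74.4%), against 16.8% of other genes. The adjusted p was 0.000107 by Fisher's exact test and 0.0015 by the shift test. They included the JNK gene bsk itself, the Fos gene kay, egr, msn, aop, Shark, dpp, tkv and zip. The strongest were the kinase gene Mkk4 (3R, 8650866 to 8651077; pooled signal 537, replicates 266 ± 47.2, SD, n = 2), jar, an unconventional myosin gene (174), raw (173) and ush (159). The replicates gave 54.3% ± 3.07 (SD, n = 2). Genes with as many annotated starts, a comparison added after the data were seen, had a promoter peak at 27.1% on average. Against these the adjusted p of the JNK list was 0.016 (permutation draws). The Jun gene Jra, puc and hep had no promoter peak in the main list.

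Polycomb group, trithorax group, Polycomb target, Notch pathway and dorsoventral patterning genes also had promoter peaks more often than other genes. Polycomb group genes had peaks at 9 of 19 (47.4%, adjusted p = 0.00834, Fisher's exact test). They were led by ph-p (993, summit 497 bp from the start) and followed by E(z) (110), Su(z)2 (95.6) and jing (84.7). The others were ph-d, Psc, Su(z)12, Sfmbt and Jarid2, while Pc and Sce had none. Trithorax group genes had peaks at 7 of 16 (43.8%, adjusted p = 0.0352, Fisher's exact test), with brm (316), fs(1)h (138), mod(mdg4) (130) and Trl (114) in front. Among developmental regulators known as Polycomb targets, 11 of 27 (40.7%, adjusted p = 0.0105, Fisher's exact test) carried a peak. They were Dll, which directs limb development (2R, 24814600 to 24814880; pooled signal 666, replicates 330 ± 183, SD, n = 2), the heart gene tin (322), salm (129), cad (89.3), eyg, mid, tup, vg, wg, Doc1 and Doc2. Notch pathway genes had peaks at 10 of 22 (45.5%, adjusted p = 0.0081, Fisher's exact test), with gro (336), Delta (169), kuz (150) and neur (142) the strongest. Dorsoventral patterning genes had 8 of 20 (40%, adjusted p = 0.0355, Fisher's exact test), with pyr (213), rho (148), sog (91.9) and Doc2 (78.4).

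These calls were less firm than those of the ribosomal protein and JNK genes. By the shift test, a permutation of gene labels, the adjusted p was 0.035 for Polycomb group genes, 0.0437 for Polycomb targets, 0.06 for the Notch list, 0.0702 for trithorax and 0.0785 for dorsoventral genes. Among the stronger 50% of peaks, Polycomb targets had 11.1% against 10.3% of other genes (adjusted p = 0.881), Polycomb group genes 15.8% (adjusted p = 0.679), dorsoventral genes 10% (adjusted p = 1) and trithorax genes 31.3% (adjusted p = 0.0708), all without a call by Fisher's exact test. Polycomb group (42.1% against 21.2%, adjusted p = 0.0859) and trithorax genes (43.8%, adjusted p = 0.102) were not called in the pooled list by Fisher's exact test. The Polycomb group list was not called in either replicate's own list, where 28.9% ± 3.72 (SD, n = 2) of its genes had a peak. Polycomb targets (25.9%, adjusted p = 0.144) and dorsoventral genes (25%, adjusted p = 0.241) were not called in the list of replicate 1, nor trithorax genes (37.5%, adjusted p = 0.108) in that of replicate 2, by Fisher's exact test. Dorsoventral genes were also not called with the 1000 bp promoter window. Against genes with a ranked peak of any strength, the Notch list (adjusted p = 0.0803), Polycomb targets and trithorax genes (both adjusted p = 0.223) and dorsoventral genes (adjusted p = 0.244) were not called by Fisher's exact test. In permutation draws of genes with as many annotated starts, a comparison added after the data were seen, the trithorax (adjusted p = 0.33) and dorsoventral (adjusted p = 0.234) lists were not called.

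Chemosensory receptor, cuticle protein, gut serine protease and histone genes had no promoter peaks in the main list. None of 179 chemosensory receptor genes (Gr10a and Gr10b are the first by symbol; adjusted p = 7.95e-14, Fisher's exact test) had one. The same held for 117 cuticle protein genes such as Ccp84Aa and Ccp84Ab (adjusted p = 8.43e-09, Fisher's exact test) and 26 gut serine protease genes such as Jon25Bi and Jon25Bii (adjusted p = 0.0381, Fisher's exact test). A count of 0, taken as fewer than 3 counts, allows shares of up to 1.68%, 2.56% and 11.5%, and the two-sided Wilson limits are 2.10%, 3.18% and 12.9%. The replicate 2 list had a peak at 1 chemosensory receptor and 1 cuticle gene, and gut proteases were not called in the list of replicate 1 (adjusted p = 0.0966, Fisher's exact test) or against genes with as many starts (adjusted p = 0.183, permutation draws). The gut protease call was also lost by the shift test (adjusted p = 0.093, permutation draws) and, by Fisher's exact test, with the 250 bp window (adjusted p = 0.0635), in the stronger 50% of peaks (adjusted p = 0.24) and against genes with a ranked peak (adjusted p = 0.244). None of 111 replication-dependent histone genes, such as His1:CG31617 and His1:CG33801, had a peak (adjusted p = 1.42e-08, Fisher's exact test; up to 2.70% allowed). These are near-identical copies in a repeat, and 2 of the 111 had a ranked peak of any strength, against 71.6% of all genes and 55.9% of chemosensory receptors, so binding at histone genes could not be assessed.

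The remaining lists gave no call in the main list. Hox cluster genes had peaks at 5 of 12 (41.7%, adjusted p = 0.0869, Fisher's exact test), with bcd (136), Ubx (102), pb (81.1) and Abd-B (79.8) the strongest. In the pooled list they were above other genes (58.3%, adjusted p = 0.0149, Fisher's exact test), as they were when each peak was given to its nearest gene (66.7%, adjusted p = 0.000945), and in the replicate 2 list they were not (16.7% against 17.2%). Acetyltransferase genes and their partners had 7 of 20 (35%, adjusted p = 0.12, Fisher's exact test), with Ing5 (233), Gcn5 (195), Sgf29 (130) and chm (117). They were called in the replicate 1 list (40%, adjusted p = 0.0112, Fisher's exact test). Of these, chm is the tagged gene itself, where a transgenic copy can add signal, and the replicate 2 list lacked its start peak. Replication initiation genes had 9 of 29 (31.0%, adjusted p = 0.103, Fisher's exact test), with Dp (157), Mcm2 (124.8), Cdc7 (84.2) and dup (82.9), but 15.5% ± 2.44 (SD, n = 2) in the replicate lists, where other genes had 13.5% and 17.2%. Cell cycle regulators had 7 of 24 (29.2%, adjusted p = 0.16, Fisher's exact test), with stg (207), Dp, dap (112) and fzr (112), and were called in the pooled list (50%, adjusted p = 0.00621) and by nearest gene (41.7%, adjusted p = 0.0149). Heat shock protein genes had 7 of 20 (35%, adjusted p = 0.12, Fisher's exact test), with Hsp83 (412), Hsp27 (352), Hsp26 (226) and Hsp22 (86.2). Ecdysone response genes had 5 of 16 (31.3%, adjusted p = 0.221, Fisher's exact test), with E23 (244), Eip75B (194), EcR (139) and Hr4 (85.6). Gap and pair-rule genes had 3 of 17 (17.6%, adjusted p = 1, Fisher's exact test), namely hry (103), cad (89.3) and knrl (73.6), and Kr and eve were among those without a peak. In the replicate lists 26.5% ± 4.16 (SD, n = 2) of them had a peak, and in the pooled list 47.1% against 21.2% of other genes (adjusted p = 0.0386, Fisher's exact test). No chorion gene of 9, such as Cp15 and Cp16 (adjusted p = 0.43, Fisher's exact test; up to 33.3% allowed), and no gene of 12 from the cellularising embryo, such as Bro and Sry-alpha (adjusted p = 0.298, Fisher's exact test; up to 25% allowed), had one.

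Markers of the cell types of the embryo were not called either in the main list, by Fisher's exact test. Neuroblast markers had peaks at 5 of 15 genes (adjusted p = 0.212, exact test), with insc (144), SoxN (133), brat (119) and pros (89.7). Glia markers had 4 of 10 (adjusted p = 0.12, exact test), namely moody (633), pnt (112), Gli (107) and loco (91.1). Tracheal markers had 4 of 11 (adjusted p = 0.155, exact test), namely bnl (143), rib (119), vvl (94.6) and pio (86.2). Muscle markers had 5 of 15 (adjusted p = 0.212, exact test), with sls (227), how (138), Tm1 (83.6) and Act57B (80.6). Germline markers had 5 of 14 (adjusted p = 0.12, exact test), with bgcn (181), CycB (110), gcl (96.2) and nanos (77.7), and 25% ± 5.05 (SD, n = 2) in the replicate lists. Neuron markers had 1 of 16 (adjusted p = 0.535, exact test), elav (311), while Appl and ChAT had none. Hemocyte markers had 1 of 12 (adjusted p = 0.728, exact test), ush (159), while Col4a1 and Hml had none. In the replicate 2 list, glia markers (50%) and ecdysone response genes (43.8%) were called (both adjusted p = 0.0478, Fisher's exact test). When each peak was given to its nearest gene, tracheal (54.5% against 17.8%, adjusted p = 0.0162) and glia markers (50%, adjusted p = 0.0409) were called by Fisher's exact test.

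Of 20 motifs, 6 were more frequent at the summits than 1000 bp away and 1 was less frequent. Flank windows were not matched for distance to a gene start, and 51.5% of summits lay at promoters. A motif common at promoters can thus be higher at summits through location alone, which was not tested. The DNA replication-related element TATCGATA lay within 100 bp of 2.98% of summits and in 0.501% of flank windows (5.95-fold, adjusted p = 3.23e-18, exact McNemar test), and core promoter Motif 1 (YGGTCACACTR) in 1.5% against 0.167% (9-fold, adjusted p = 1.14e-11). GAGA repeats, bound by the Trl product GAGA factor, were at 8.39% of summits against 4.0% (adjusted p = 5.91e-16, exact McNemar test) and CA repeats at 8.80% against 4.77% (adjusted p = 1.6e-12). A CTCF core was at 4.41% against 2.55% (adjusted p = 1.46e-05, exact McNemar test) and the core promoter E-box CAGCTGNTT at 3.15% against 2.00% (adjusted p = 0.00341). In the replicates' own lists, the DRE was at 2.94% ± 0.395 of summits and GAGA at 8.47% ± 1.94 (SD, n = 2). The ecdysone receptor core site AGGTCA was less frequent at summits, 3.58% against 5.17% (adjusted p = 0.00137, exact McNemar test). AP-1 sites, the binding site of Jun and Fos, were in 1.79% of summit windows and 2.07% of flanks, and the Pho core in 8.32% and 8.77% (both adjusted p = 0.565, exact McNemar test). The early zygotic TAGteam site (1.26% and 1.19%), TATA (2.96% and 2.79%), GATA (13.1% and 14.0%), E2F (2.17% and 1.72%), Inr, CACGTG, Mad/Brk, twi E-box, BEAF pair, Motif 6 and the TTAGGGTTA control were not called either. With the bases of each motif in reversed order, the DRE, CTCF core and E-box were not called. But 6 motifs were again higher at summits, 4 of 18 without GAGA and CA repeats. These were CACGTG (7.46% against 4.12%, adjusted p = 2.93e-10), the twi E-box (8.41% against 5.41%, adjusted p = 4.1e-07; both exact McNemar test), Inr and Motif 1 (0.334% against 0.0238%). Reversed Motif 1 still holds the stretch TCACACT of Motif 1, so it is no control for that motif. As the other reversed motifs show, a call at summits is not by itself particular to a motif's sequence. Reversed AGGTCA was lower at summits like AGGTCA itself (6.98% against 8.46%, adjusted p = 0.0346, exact McNemar test).

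**Figure D4:**
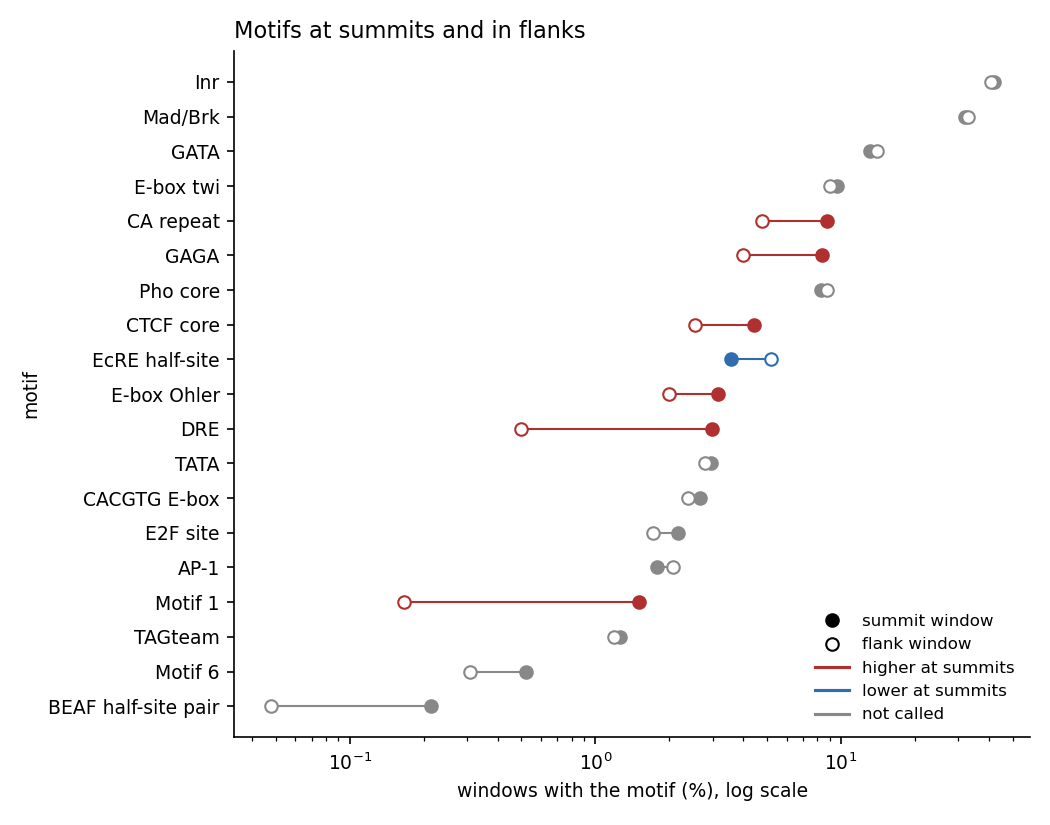
Percent of windows with each motif (log scale) at summits (filled circles) and in flanks 1000 bp away (open circles) over 4195 peaks; red lines mark motifs higher at summits, blue lower, grey not called by the exact McNemar test. The DRE rises from 0.501% to 2.98% and Motif 1 from 0.167% to 1.5%.

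Bound promoters also differed in sequence from unbound ones, but the starts were not chosen alike. Choosing the start nearest a summit in bound genes only can itself raise the shares of motifs frequent at summits, which was not tested. Within 250 bp of the start, 16.1% of 2350 bound and 6.63% of 11618 unbound promoters had a GAGA repeat (odds ratio 2.71, adjusted p = 2e-43, Fisher's exact test), and 14.6% against 7.24% a CA repeat (adjusted p = 1.77e-26). The E-box CAGCTGNTT (12.1% against 7.61%, adjusted p = 2.69e-11), DRE (12.04% against 9.13%, adjusted p = 4.51e-05) and Motif 1 (6.47% against 4.30%, adjusted p = 3.22e-05) were more frequent by Fisher's exact test. CACGTG (8.85% against 6.57%), E2F (6.81% against 4.89%), Mad/Brk (63.7% against 57.9%) and CTCF (5.57% against 4.30%) sites were also more frequent, the last not in the replicate 2 list (adjusted p = 0.233, Fisher's exact test). Among the stronger 50% of peaks neither Motif 1 (5.57% against 4.55%, adjusted p = 0.131) nor CTCF (adjusted p = 0.539) was called by Fisher's exact test. TATA boxes were less frequent, at 7.57% of bound and 13.5% of unbound promoters (odds ratio 0.524, adjusted p = 4.71e-16, Fisher's exact test). Also less frequent were Inr (71.3% against 77.3%, adjusted p = 2.57e-09), GATA (26.3% against 32.2%, adjusted p = 7.31e-08) and AGGTCA (8.21% against 10.7%, adjusted p = 0.0004) sites by Fisher's exact test. Pho, AP-1, TAGteam and twi E-box sites, Motif 6, the BEAF pair and the TTAGGGTTA control gave no call.

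Small RNA genes and long non-coding RNA genes carried peaks beyond their share of the genome. Within 500 bp of tRNA gene starts lay 34 summits, 5.05 times the number their bases would give (adjusted p = 1.95e-13, exact binomial test), at 50 of 290 tRNA genes. The excess was 5.07-fold for snoRNA genes (25 summits, adjusted p = 2.31e-10) and 5.60-fold for snRNA genes (5 summits, adjusted p = 0.00272) by exact binomial tests. It was 2.91-fold for miRNA precursors (20 summits, adjusted p = 4.99e-05) and 2.72-fold for lncRNA genes (161 summits, adjusted p = 1.46e-27), by the same exact test. Among the 2036 summits outside protein-coding promoters the excess remained, at 7.77-fold for tRNA (25 summits), 6.23-fold for snoRNA (14 summits) and 3.94-fold for lncRNA genes (110 summits). No summit lay within 500 bp of the 99 annotated rRNA genes, which are repeated (adjusted p = 0.641, exact binomial test). Counted per gene, a peak was at 17.2% of tRNA, 15.6% of snRNA, 10.4% of snoRNA and 7.4% of lncRNA genes and at 17 of 260 miRNA precursors. Protein-coding genes had a promoter peak at 16.8%. Of these classes only tRNA genes thus reached the protein-coding share, and the shares were not tested against each other.

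The tagged gene itself carried several peaks. Around chm (2L, 7412417 to 7422736, plus strand, dm6) the main list had 4 peaks. They lay at the start (7412200 to 7412535, summit 49 bp from the chm start, pooled signal 117, replicates 55.5 ± 8.65), at 2 intragenic sites (7418430 to 7418765, signal 94.2, replicates 49.8 ± 9.16; and 7420694 to 7421029, signal 132, replicates 65.2 ± 3.31) and past the 3' end (7423422 to 7423757, signal 132, replicates 67.1 ± 4.47; all SD, n = 2). Replicate 1's list had 5 peaks there and replicate 2's had 2, the latter without the peak at the start. As many peaks within 2000 bp of the gene were found for 290 of 13968 protein-coding genes (2.08%). This count grows with gene length; among 633 other genes within 20% of the length of chm, a comparison added after the data were seen, 20 (3.16%) had as many. A transgenic copy of the gene can add signal at its own locus.

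**Figure D5:**
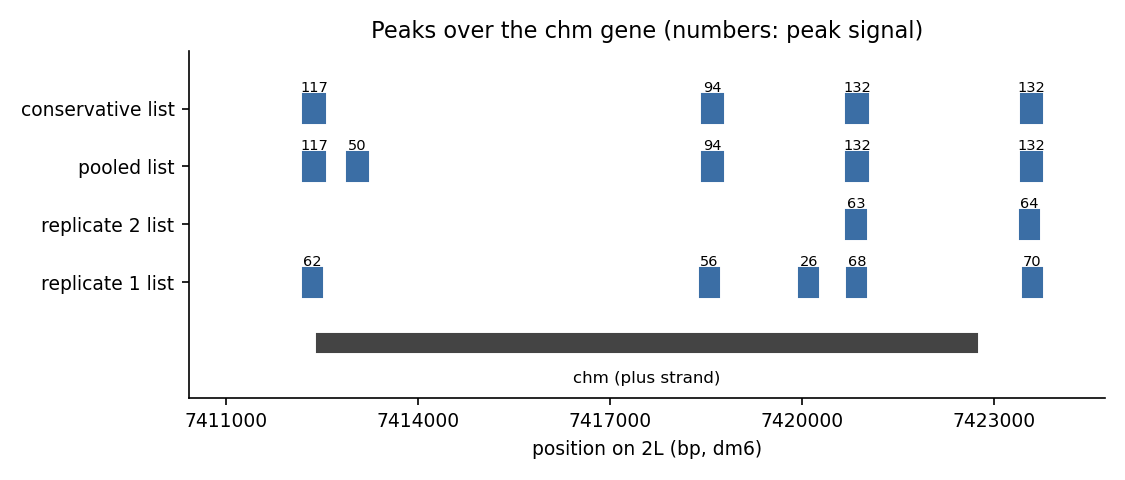
Peaks (blue boxes, with their signal) over the chm gene (grey bar) on 2L in 4 lists; the horizontal axis is the position in bp (dm6). The conservative list has 4 peaks and the replicate 2 list 2, and signals compare only within a list.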

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

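Peaks on sequences outside the 7 tested arms stood out because no comparison used them. The main list had 7 peaks on 7 unplaced sequences assigned to the X, with signals from 57.4 to 115.4. Their number passed the limit of 3 used for a count of 0. No expected number was set, so this is no test, and the ranked list that pairs the replicates held 1654 peaks outside the tested arms. The replicate 1 list had 18 peaks outside the tested arms, the replicate 2 list 2 and the pooled list 19. No explanation was tested.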

How the results depend on the processing

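Alternatives were planned before the data were examined, except leaving out peaks of signal under 20, matching genes on their number of starts, the single-replicate versions of the chromosome, non-coding and signal results, the replicate correlation within conservative peaks, and genes of the length of chm. The promoter excess stayed above 1 under all settings run, from 3.08-fold with a 1000 bp window to 7.36-fold with 250 bp. The lists of ribosomal protein, JNK, chemosensory and cuticle genes were called in all 11 other settings. Of 85 other values of main results, which for gene lists are counts of lists, 75 stayed within the limits set for them. List by list, calls were kept in 100 cases, lost in 31 and turned in direction in 1. The pooled list also had 8 lists above, but lost Polycomb group, trithorax and translation initiation genes and added Hox, cell cycle and gap and pair-rule genes. The number of genes with a promoter peak was 1435 among the stronger 50% of peaks, by construction, against 2350, and 1881 to 2400 in the single replicates. The lists above other genes numbered 3 in the stronger 50% of peaks, 4 against genes with a ranked peak (2 below), 5 against genes matched on their number of starts, 5 to 7 in the single replicates and 11 by nearest gene, which added Hox, cell cycle, glia and tracheal genes and lost translation initiation factors, against 8. Motifs less frequent at summits numbered 2 in the stronger 50%, against 1. The replicate rho was 0.49 in conservative peaks and 0.378 over all ranked pairs. As many peaks as at chm were found at 3.16% of genes of its length, against 2.08% of all. Directions turned as follows. Hox genes had 16.7% to 41.7% with a peak in single replicates. In the stronger 50% of peaks replication initiation had 6.9%, gap and pair-rule genes 5.88% and dorsoventral genes 10%, against 10.3% of others. Gap and pair-rule genes had 17.6% with a 1000 bp window (others 19.3%) and 20% among genes with a ranked peak (others 25.5%), and neuron markers had 18.8% by nearest gene (others 17.8%). The cause was not tested. With bases reversed, 6 motifs were higher at summits. Among them were GAGA and CA repeats, which reversal leaves nearly the same, and Motif 1, which keeps the stretch TCACACT. Read depth is unknown, so no limit on weak sites can be given.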

Other observations

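The tests of shoulder peaks and of housekeeping expression, and the summaries of replicate differences, sequence composition and transposons, were chosen after the results were seen. Peaks found in only 1 replicate (no base of overlap with the other list) differed in place. Of 1481 peaks of replicate 1 alone, 30.5% were at promoters and 22.1% intergenic, against 52.9% and 9.15% of 2022 peaks of replicate 2 alone (adjusted p = 1.91e-39 and 3.56e-26, Fisher's exact test over peaks of these 2 libraries). GAGA repeats lay at 7.16% of the former and 11.6% of the latter (adjusted p = 1.7e-05), and the DRE at 1.28% and 2.87% (adjusted p = 0.00226), by Fisher's exact test. Few summits lay in annotated transposons, 7 of 4195 (0.167%) in sequence that makes up 5.93% of the genome. Among ranked peaks of any strength the share was also low, 0.833%. Whether peaks can be called in repeats was not tested, so binding at transposons could not be assessed.

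The strongest peaks were rich in A and T. In the 420 strongest peaks of the main list (signal 213 or more) the sequence within 100 bp of the summit was 38.2% G and C, against 44.8% in the 419 weakest, and the Spearman rho between signal and GC content was -0.246 over peaks, -0.213 at promoters and -0.31 elsewhere. CA repeats were at 4.29% of the strongest and 10.5% of the weakest. Among 14915 8-mers within 50 bp of summits, CAACACTG had the smallest p, in 1.53% of summit windows against 0.215% of flanks (adjusted p = 2.97e-07, Fisher's exact test), followed by TATCGATA, ATCGATAG and GAGCGAGA. Unlike the McNemar test of the motifs, this test ignored the pairing of each summit with its flank.

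The main list holds 146 peaks with a pooled signal under 20, although their matched replicate signals (median 46.3) resemble those of the other peaks (49.2). A candidate explanation is that they are shoulders of a stronger peak to which the replicate peaks were matched: 97.9% overlap a stronger peak of the list, against 2.32% of the other peaks. Only 2.05% had matched replicate signals of their own, but this decides nothing, since the matching can give an overlapping peak the signals of its neighbour. Shoulders and weak binding sites of their own cannot be told apart here for that reason. A first test, which compared these medians, was set aside on the same ground.

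Ribosomal protein genes had promoter peaks at 75.6%. More annotated starts per gene would not give this, since genes drawn with the same numbers of starts had a peak at 21.3% on average (highest of 10000 draws 37.8%). Genes matched on whether another gene starts within 1000 bp had 18.9% (highest 35.4%). Proteasome and oxidative phosphorylation genes did not share the excess, with a peak at 16 of 132 (12.1%, odds ratio 22.5, p = 2.04e-21, Fisher's exact test against ribosomal protein genes). This does not decide on housekeeping use as such, since the comparison was chosen after both shares were seen. The proteasome list, matched by name, also holds members without a peak such as Prosalpha3T and Rpt3R, whose use in all tissues was not checked. Very high transcription or open chromatin, which can raise signal in any immunoprecipitation, was not tested and stays open, as does recruitment of chm.

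Peaks over chm may come from an extra transgenic copy of its region, which would raise weak signal in the flanks too. From 2000 to 10000 bp outside the gene lay 26 ranked peaks against a median of 17 for protein-coding genes, more than at 90.9% of genes, which is short of the 95% set beforehand and above the 50% that would argue against it. The copy and binding at the gene cannot be told apart here, since the peak lists hold no input signal.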
